A study of Homo sapiens with 7 samples.

How the data were processed

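Gene expression was measured on 7 single-colour Affymetrix expression arrays of human RNA, 3 of the glioblastoma cell line U87 and 4 of MGH87GSC, the glioma stem cell spheres grown from U87 tumours in the brains of immunodeficient mice. Per the labels' protocols, RNA was isolated with a column kit, passed an integrity threshold and was enzymatically labelled with biotin. The values used were the authors' deposited values, 1 per probe set and array, on a log2 scale. Partek and GCRMA are the tools named, per the submitters' processing notes, and their versions, role and order are not given in the sources used here. The log2 scale was inferred from the values themselves, which ran from 3.79 to 14.90, and higher values were read as more RNA. The column means of the 7 arrays were equal, at 6.67, and genes were not centred. The medians of the arrays were 6.12 (U87 1), 5.87 (U87 2), 5.88 (U87 3), 5.87 (MGH87GSC 1), 5.95 (MGH87GSC 2), 5.89 (MGH87GSC 3) and 5.90 (MGH87GSC 4). Scanner files were not used here and detection calls were not used here, so the background of each array was not measured. The number of arrays limits the precision.

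Groups and replicate numbers were taken from the sample titles and descriptions. The array labelled MGH87GSC 1 is described as spheres of the first tumour, and MGH87GSC 2, 3 and 4 as spheres of the second, serially implanted tumour. The design text places the work in 2 batches, the first with U87 and the first implant and the second with duplicate U87 and triplicate second-implant spheres, and it does not say which U87 array belongs to the first. The replicate numbers shared by the groups did not pair the arrays, because the deviations of same-numbered arrays from their group means did not correlate positively in every pair. No label says that arrays of a group came from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical.

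The platform table held 54675 probe sets. The platform annotation used here gave 1 gene symbol for 41097 of them and several for 1801, and 11777 were not listed and are unnamed here. Symbols were updated through gene identifiers against the GRCh38.p14 RefSeq gene table, which matched 41043 probe sets, and no coordinates of that table are printed. Probe sets with a log2 value above 4 on at least 3 arrays were kept, which removed 3 probe sets. Each gene was represented by the probe set with the highest mean over the 7 arrays, giving 19775 genes, and 10523 genes had more than 1 probe set. Probe sets whose identifiers end in _x_at or _s_at can bind transcripts of related genes, and values of such families are uncertain.

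Differences were fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on the log2 values with two-sided tests. A gene passed the threshold at a Benjamini-Hochberg adjusted p below 0.05. The comparison of MGH87GSC with U87 used a fit of both groups. The comparisons of the second implant, the first implant and U87 used 1 fit of 3 groups over all 7 arrays, in which the single first-implant array was assumed to vary like the others. Tests, groups, gene lists, alternatives and the rule for named genes were fixed before the data were examined. There were 42 gene lists with 858 different members, of which 793 were measured. Lists were tested with limma's camera at a preset correlation of 0.01, again with a correlation estimated per list, and with fry, which tests whether the genes of a list move on balance one way. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

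The rule for named genes took the 10 largest rises and 10 largest falls among genes past the threshold, with every array of one group on one side of every array of the other and a mean of at least 6 in the higher group. It left out uncharacterised names, added 12 genes named whatever they did and up to 4 members of each list past the threshold and of the stem cell, glioma subtype and other-cell-type lists, and took 5 genes per direction between the implants. For MGH87GSC against U87 no gene passed the threshold, so the rule gave none there. After this was seen, the same rule and the list test were applied to the second implant against U87. Among the 12 genes, BMI1 and POU5F1 were not analysed here because their probe sets carry several symbols. A few further genes, each stated as such, were chosen after their values were seen.

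The fitting steps were tested on simulated data with the means and spreads of the 19775 genes and 200 changed genes. For MGH87GSC against U87, 32.0% of changes of log2 1 and 85.0% of changes of log2 2 were recovered. For the second implant against U87 the shares were 25.0% and 86.5%. Between 1 and 8 unchanged genes were called in each simulation. The noise was drawn independently for each gene and array, and every array of the changed group was shifted alike. The simulated data thus held no technical batch and no MGH87GSC array lying with U87. These shares therefore do not give the recovery or the false calls in the real data.

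The alternatives covered the replicate number as a block, the design text's batch as a block with each U87 array in turn placed in the first batch, no filter and a stricter filter, quantile normalization, median centring, the mean of all probe sets of a gene, an intensity trend with a robust prior, no moderation of the variance, and leaving out each array. Fits with the batch read from the poly-A spike-in controls as a block, fits on the 5 arrays with high 5′ spike-in signal and the same fits without the array labelled MGH87GSC 1 were added after seeing the data.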

Results

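The series compared U87, an established human glioblastoma cell line, with MGH87GSC, spheres enriched for glioma stem cells that were grown from tumours formed by U87 cells in mouse brain. The title of the series names the enrichment of glioma stem cells by implantation into the brain as its purpose. Expression values on a log2 scale were analysed for 3 U87 arrays and 4 MGH87GSC arrays, 1 labelled as the first implant and 3 as the second, serial implant. After 1 probe set was taken per gene, 19775 genes were compared.

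The arrays did not group by label alone. The array labelled MGH87GSC 1 differed from U87 2 and U87 3 by a root mean square of 0.12 (log2, mean of both), and U87 2 and U87 3 differed from each other by 0.13. MGH87GSC 3 and 4 differed from U87 2 and 3 by 0.57 and from each other by 0.12. Over genes, which are not independent replicates, the array labelled MGH87GSC 1 correlated with U87 2 at r = 0.999 and with MGH87GSC 2, 3 and 4 at r = 0.957 to 0.968. The first principal component held 57.2% of the variance and placed the array labelled MGH87GSC 1 (-30.1) beside U87 2 (-29.9) and U87 3 (-30.6) and near U87 1 (-44.4), away from MGH87GSC 2, 3 and 4 (43.1, 45.7 and 46.2). The second component held 38.4% and set U87 1 (65.9) and MGH87GSC 2 (26.5) apart from the other 5 arrays (-28.2 to -5.99).

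The bacterial poly-A controls, RNAs added before labelling to follow the reaction, divided the arrays in the way of the second component. Their 3′ probe sets exceeded their 5′ probe sets by 2.59 (log2) on U87 1 and 2.43 on MGH87GSC 2. The same difference was 0.98 on U87 2, 1.06 on U87 3, 0.96 on the array labelled MGH87GSC 1, 1.08 on MGH87GSC 3 and 1.05 on MGH87GSC 4. U87 1 and MGH87GSC 2 are treated here as a technical batch that holds 1 array of each group, and medians within and outside it are given for each list past the threshold in the second implant. U87 1 also had the narrowest spread of values, with an SD of 1.76 over probe sets against 1.98 to 2.06 on the other arrays.

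**Figure D1:**
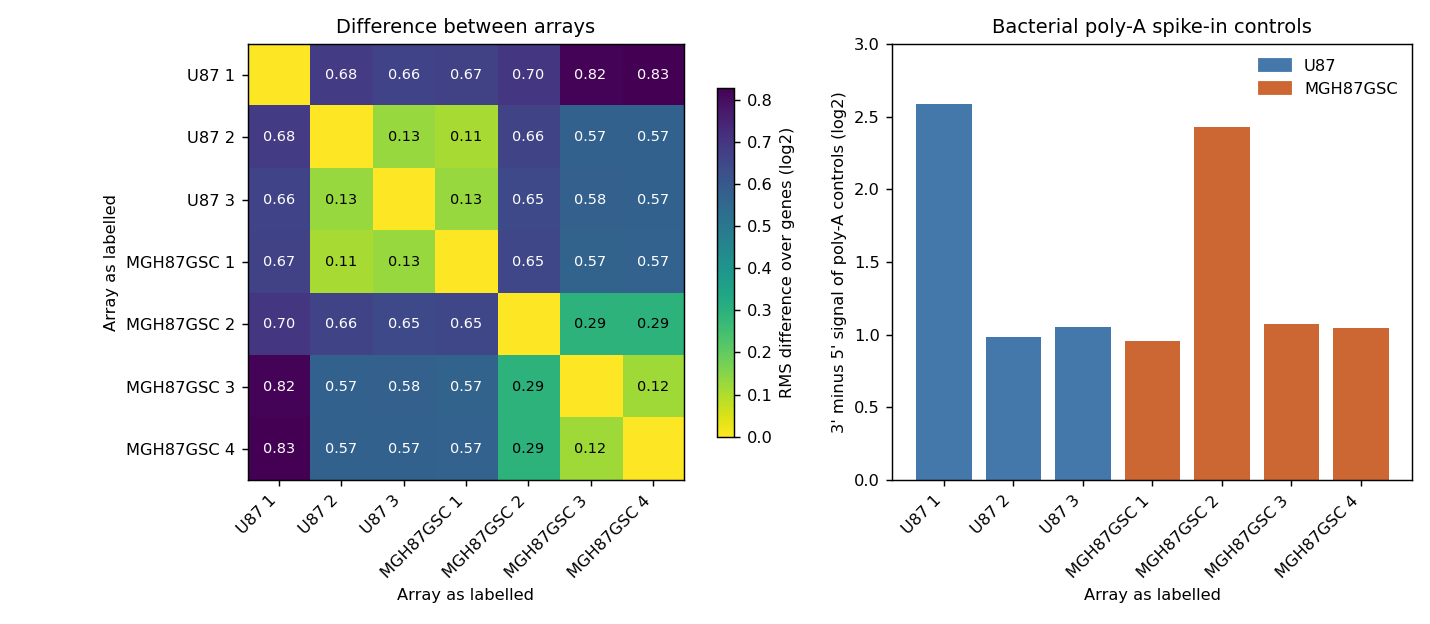
Left, root mean square difference (log2) over genes between each pair of the 7 arrays, darker for larger. Right, bars of the 3′ minus 5′ signal (log2) of the bacterial poly-A controls on each array, with U87 in blue and MGH87GSC in orange, 2.59 on U87 1, 2.43 on MGH87GSC 2 and 0.96 to 1.08 on the others.

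The first comparison was that of all MGH87GSC arrays with U87, the contrast of spheres with their parental line. The DNA replication list was lower in MGH87GSC, with a median change of -1.50 (log2) over 31 measured genes (camera adjusted p = 1.14e-15, adjusted p = 0.531 with an estimated correlation). None of the lists that follow passed with an estimated correlation either (adjusted p of 0.531 to 0.688). Lists for ER chaperones (median 0.51, adjusted p = 6.74e-06), the amino acid and ATF4 response (0.46, 9.32e-06), matrix glycoproteins and proteoglycans (0.49, 0.000897) and MHC class I and antigen presentation (0.42, 0.00129) were higher, and metallothioneins (-0.53, 0.000648) and DNA repair genes (-0.39, 0.000897) were lower. Oxidative phosphorylation subunits (0.19, 0.00129), mesenchymal glioma genes (0.24, 0.00807), hypoxia response genes (0.32, 0.00887), ABC transporters (0.28, 0.0127), NF-kB targets (0.38, 0.0211), p53 targets (0.29, 0.0211) and matrix proteases (0.23, 0.0215) were higher, and mitosis genes (-0.22, 0.00887) and heat shock genes (-0.43, 0.0215) were lower. Adjusted over the list alone, 11 ATF4 response genes, 8 ER chaperones, and 10 hypoxia genes rose and 1 hypoxia gene fell. The collagen list did not pass (camera adjusted p = 0.190), although 7 collagens rose and 2 fell adjusted over the list alone. Of 42 lists, 17 passed the threshold, 11 higher and 6 lower in MGH87GSC. Without U87 1 only 7 passed, 2 higher and 5 lower, and the calls of the pluripotency, mesenchymal, hypoxia, oxidative phosphorylation, MHC class I, NF-kB, matrix glycoprotein, matrix protease, ABC transporter and p53 lists ended (adjusted p of 0.0700 to 0.461). The medians without U87 1 were 0.42 for matrix glycoproteins, 0.245 for ABC transporters, 0.21 for matrix proteases, 0.28 for MHC class I, 0.25 for NF-kB, 0.23 for hypoxia, 0.14 for mesenchymal genes, 0.11 for p53, 0.0755 for oxidative phosphorylation and 0.056 for pluripotency. With quantile normalization 9 passed (4 higher and 5 lower) and with the strict filter 11 (5 higher and 6 lower). The calls of the mitosis and heat shock lists ended without U87 2, without U87 3 and without MGH87GSC 2 (medians of -0.12, -0.11 and -0.16 for mitosis and -0.34, -0.35 and -0.35 for heat shock), and that of the NF-kB list without MGH87GSC 2 (0.27). With a correlation estimated per list 0 of the 42 passed, and by fry 0.

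No single gene passed the threshold in this comparison. The mean of UHRF1, which recruits the maintenance DNA methyltransferase, differed by -3.73 ± 1.19 (SE, limma, n = 4 against 3, adjusted p = 0.283), and that of GDF15, a secreted stress-response cytokine, by 3.10 ± 0.88 (adjusted p = 0.283). The SDs of these genes over the 4 MGH87GSC arrays were 2.53 and 1.85, because the array labelled MGH87GSC 1 gave 11.42 for UHRF1 and 9.10 for GDF15 while U87 averaged 11.36 and 8.77. limma called 0 genes (smallest adjusted p = 0.283), and 3150 genes had an unadjusted p under 0.05 where chance gives 989. The groups did not overlap in 1462 genes, 7.39% against 5.71% by chance. Without the array labelled MGH87GSC 1 the comparison is that of the second implant with U87 and called 3373 genes.

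The genes named whatever they did included the stem cell and glioma genes most often read in such spheres. PROM1, which encodes the surface marker CD133, averaged 4.76 ± 0.21 (SD, n = 3) in U87 and 4.61 ± 0.09 (n = 4) in MGH87GSC, and the U87 value lay at the 8.64th percentile of probe sets. The differences, MGH87GSC minus U87, were -0.07 for NES (nestin), -0.16 for SOX2, 0.19 for OLIG2, -0.40 for MSI1, 0.05 for NANOG, 0.07 for GFAP and -0.14 for EGFR. None of these passed the threshold (limma adjusted p of 0.679 to 0.899), and the 95% interval of the difference was -0.49 to 0.18 for PROM1, -0.45 to 0.31 for NES and -0.56 to 0.23 for SOX2. CD44, an adhesion receptor, differed by -0.40 (adjusted p = 0.284) and VEGFA, an angiogenic growth factor, by -0.78 (adjusted p = 0.283). The list of neural and glioma stem cell markers did not pass (26 measured, median -0.09, camera adjusted p = 0.427), and the pluripotency list was lower (11 measured, median -0.22, adjusted p = 0.0261), with 0 members past the gene threshold. Its call is among those lost with an estimated correlation (adjusted p = 0.531). Without U87 1 the median was 0.056 (adjusted p = 0.397). In the second implant it was -0.50 between MGH87GSC 2 and U87 1, the technical batch, and -0.045 between MGH87GSC 3 and 4 and U87 2 and 3.

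The comparison of the second implant with U87 asked the same of the 3 serially implanted sphere arrays. UHRF1 fell most, from 11.36 ± 0.24 (SD, n = 3) in U87 to 6.38 ± 0.18 (n = 3), 31.7-fold, with a change of -4.99 ± 0.17 (SE, limma adjusted p = 9.69e-05). GDF15 rose most, from 8.77 ± 0.35 to 12.79 ± 0.04, a change of 4.02 ± 0.19 (adjusted p = 0.000197). The DNA replication list was lower, and the lists of the ATF4 response, ER chaperones and matrix glycoproteins were higher, by camera, although each had an adjusted p = 0.703 with an estimated correlation. limma called 3373 genes, 2027 higher and 1346 lower in the second implant, of which 1011 and 606 changed by at least log2 1. The groups did not overlap in 6624 genes, 33.5% against 10% by chance.

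The other largest falls were those of MCM10 (-4.71), CCNE2 (-4.09), DCLK1 (-3.85), CDC6 (-3.82), MT1M (-3.81), GINS2 (-3.56), DTL (-3.50), ZNF367 (-3.47) and MCM5 (-3.33). MCM5 encodes a subunit of the replicative helicase, CDC6, MCM10 and GINS2 encode proteins that load or activate it, CCNE2 encodes cyclin E2, and MT1M is a metallothionein. The other largest rises were those of IL1A (3.91), INHBE (3.90), CD24 (3.86), EFEMP1 (3.60), KCNE4 (3.55), SLC1A1 (3.34), ID3 (3.31), TXNIP (3.30) and MCEE (3.27). IL1A encodes an inflammatory cytokine, INHBE an activin subunit, CD24 a surface glycoprotein, SLC1A1 a glutamate transporter and ID3 an inhibitor of basic helix-loop-helix factors. Adjusted p for these 18 genes lay between 9.69e-05 and 0.00147. MCM10 in the second implant (12.7th percentile of probe sets) and INHBE in U87 (23.8th) lay among the dim probe sets, so the sizes of their changes are uncertain. Probe sets of 1 gene disagreed in sign for DCLK1 (2 of 4 with the reported sign) and GINS2 (2 of 3). The mean over probe sets was 1.54 for GDF15, 2.22 for IL1A, -0.86 for DCLK1 and -1.39 for GINS2.

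**Figure D2:**
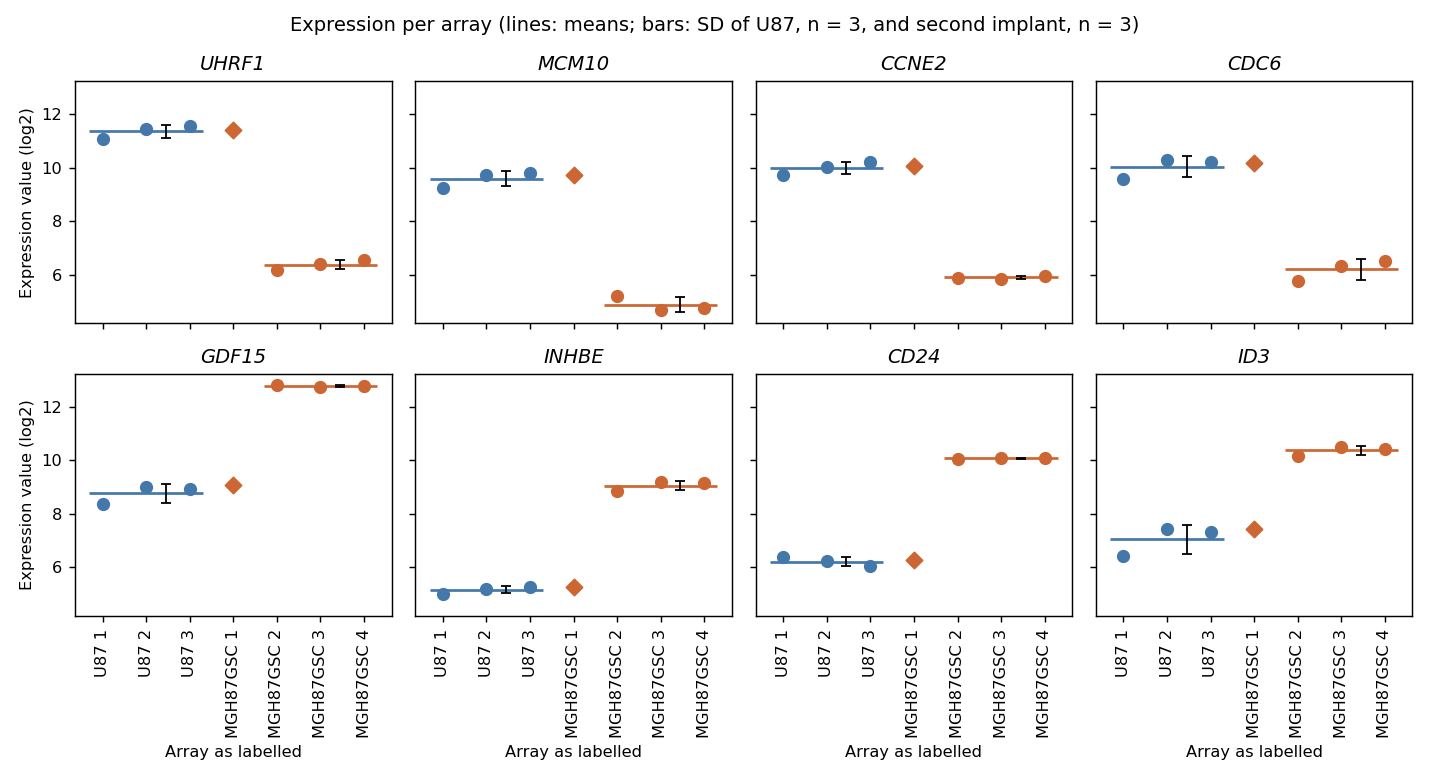
Expression value (log2) of 8 genes on each of the 7 arrays, with U87 in blue, MGH87GSC in orange and the array labelled MGH87GSC 1 as a diamond. Lines are the means and bars the SDs of U87 (n = 3) and the second implant (n = 3), such as 11.36 and 6.38 for UHRF1.

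Of 31 measured DNA replication genes, 30 fell and 0 rose (30 fell adjusted over the list alone), with a median change of -2.14 (camera adjusted p = 4.89e-31, adjusted p = 0.703 with an estimated correlation). MCM2, a helicase subunit, fell by 2.54 ± 0.28 (SE) and PCNA, the sliding clamp of DNA polymerases, by 1.23 ± 0.16, both chosen after their values were seen. Of 30 mitosis genes 10 fell and 0 rose, with a median of -0.36 (adjusted p = 0.000178, 0.715 with an estimated correlation). KIF11 (-1.31), BUB1B (-1.22), CDK1 (-1.18) and CDCA8 (-1.17) fell. The median of the replication list was -2.36 between MGH87GSC 3 and 4 and U87 2 and 3, and -1.79 between MGH87GSC 2 and U87 1. For the mitosis list these medians were -0.54 and -0.01.

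Among 19 DNA repair genes 7 fell and 0 rose (11 fell adjusted over the list alone), with a median of -0.57 (camera adjusted p = 5.50e-06, 0.703 with an estimated correlation). EXO1 (-2.39), BRCA1 (-2.30), RAD51AP1 (-2.18) and XRCC2 (-1.76) fell. Of 24 chromatin regulators 8 fell and 3 rose, with a median of -0.42 (adjusted p = 0.0239, 0.715 with an estimated correlation). Besides UHRF1, the helicase gene HELLS (-2.48), the polycomb methyltransferase gene EZH2 (-2.05) and TET3 (-1.33) fell, and a probe set of TET3 had the other sign (0.010). Medians between MGH87GSC 3 and 4 and U87 2 and 3 were -0.69 for DNA repair and -0.46 for chromatin regulators. Between MGH87GSC 2 and U87 1 they were -0.34 and -0.23. The call of the chromatin list ended without U87 2 (median -0.27, adjusted p = 0.0536) and without U87 3 (median -0.25, adjusted p = 0.0558).

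Of 28 genes of the amino acid and ATF4 response 13 rose and 2 fell, with a median of 0.52 (camera adjusted p = 5.80e-06, 0.703 with an estimated correlation). CTH (2.20 ± 0.16, SE), ALDH1L2 (2.02 ± 0.22), CHAC1 (1.88 ± 0.15) and DDIT4 (1.86 ± 0.16) rose. ER chaperones and related genes rose in 10 of 18 cases and fell in 0, with a median of 0.65 (adjusted p = 5.54e-06, 0.703 with an estimated correlation). HERPUD1 (2.15), DNAJB9 (1.69), XBP1 (1.09) and HSPA5 (1.02), the chaperone BiP, rose, and a second probe set had the other sign for HERPUD1 and XBP1. Medians between MGH87GSC 3 and 4 and U87 2 and 3 were 0.40 for the ATF4 list and 0.58 for ER chaperones. Between MGH87GSC 2 and U87 1 they were 0.77 and 0.80.

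Heat shock genes moved the other way, with 6 of 11 falling and 1 rising and a median of -0.59 (camera adjusted p = 0.00767, 0.703 with an estimated correlation). HSPH1 (-1.21), CHORDC1 (-1.12) and HSP90AA1 (-0.80) fell, and CRYAB, a small heat shock protein gene, rose by 1.74. Metallothioneins and zinc transport genes fell in 5 of 8 cases and rose in 0 (7 fell adjusted over the list alone), with a median of -0.74 (adjusted p = 5.50e-06, 0.703 with an estimated correlation). MT1M (-3.81), the zinc exporter gene SLC30A1 (-1.77), MT1E (-1.47) and MT1G (-0.81) fell, and the metallothionein probe sets can bind transcripts of several family members. Medians between MGH87GSC 3 and 4 and U87 2 and 3 were -0.63 for heat shock genes and -0.81 for metallothioneins. Between MGH87GSC 2 and U87 1 they were -0.34 and -0.62.

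Matrix glycoproteins and proteoglycans rose in 14 of 27 cases and fell in 2, with a median of 0.63 (camera adjusted p = 0.000178, 0.703 with an estimated correlation). EFEMP1 (3.60), IGFBP3 (2.11), NID2 (1.64) and SPARC (1.62) rose. ABC transporters and drug metabolism genes rose in 10 of 25 cases and fell in 0, with a median of 0.38 (adjusted p = 0.00626, 0.703 with an estimated correlation). The cholesterol exporter gene ABCA1 (1.90), the aldo-keto reductase genes AKR1C3 (1.72) and AKR1C2 (1.15), and GSTT1 (1.11) rose, and a second probe set of GSTT1 had the other sign. Medians between MGH87GSC 3 and 4 and U87 2 and 3 were 0.57 for the matrix list and 0.30 for ABC transporters. Between MGH87GSC 2 and U87 1 they were 0.75 and 0.34.

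A further 8 lists passed the threshold with all arrays and lost the call without U87 1 (adjusted p of 0.0510 to 0.420), which also left fewer arrays. Their medians with all arrays and without U87 1 were 0.39 and 0.29 for hypoxia, 0.53 and 0.36 for NF-kB, 0.56 and 0.37 for MHC class I, 0.27 and 0.18 for mesenchymal genes, 0.26 and 0.28 for matrix proteases, 0.33 and 0.15 for p53, 0.22 and 0.081 for oxidative phosphorylation and 0.19 and 0.18 for pericyte markers. Between MGH87GSC 3 and 4 and U87 2 and 3 the medians were, in the same order, 0.30, 0.39, 0.40, 0.21, 0.26, 0.16, 0.098 and 0.11. Between MGH87GSC 2 and U87 1 they were 0.79, 0.60, 0.66, 0.41, 0.42, 0.47, 0.39 and 0.26. Hypoxia response genes rose in 11 of 23 cases and fell in 4 (camera adjusted p = 0.0124, 0.739 with an estimated correlation). LOX, a collagen crosslinking enzyme gene, rose by 2.56, DDIT4 by 1.86, MXI1 by 1.76 and INSIG2 by 1.37, whereas VEGFA fell by 1.02 ± 0.14 (SE, limma adjusted p = 0.00341). NF-kB targets and inflammatory cytokines rose in 11 of 25 cases and fell in 1 (adjusted p = 0.00546, 0.703 with an estimated correlation), among them IL1A (3.91), ICAM1 (1.90), CCL5 (1.72) and CCL2 (1.61). MHC class I and antigen presentation genes rose in 7 of 16 cases and fell in 1 (adjusted p = 0.00229, 0.703 with an estimated correlation), with IRF1 at 1.39, HLA-F at 0.83, HLA-E at 0.69 and TAP2, which fell, at -0.81. The HLA probe sets can bind several class I transcripts.

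Mesenchymal glioma genes rose in 7 of 27 cases and fell in 3 (camera adjusted p = 0.00767, 0.715 with an estimated correlation), with COL1A2 at 2.05, COL5A1 at 1.34, TGFBI at 1.251 and THBS1, which fell, at -1.21. Matrix proteases and inhibitors rose in 9 of 26 cases and fell in 4 (adjusted p = 0.0442, 0.715 with an estimated correlation), with TIMP3 (2.31), CTSK (2.22), MMP1 (2.16) and MMP14 (1.61) the largest. Targets of p53 and cell cycle inhibitors rose in 6 of 21 cases and fell in 1 (adjusted p = 0.0472, 0.739 with an estimated correlation). CDKN1C (1.56), CDKN1A (1.43) and ZMAT3 (1.36) rose and TP53I3 fell (-1.19). Oxidative phosphorylation subunits shifted by a median of 0.22 with 1 of 36 rising (SDHA, 1.10) and 1 falling (CYCS, -0.46; adjusted p = 0.0239, 0.801 with an estimated correlation). The oxidative phosphorylation call also ended with the mean over all probe sets of a gene (median 0.12, adjusted p = 0.167), with quantile normalization (0.11, adjusted p = 0.168), with the strict filter (0.22, adjusted p = 0.211) and without MGH87GSC 3 (0.18, adjusted p = 0.0650). Pericyte and fibroblast markers rose in 5 of 14 cases and fell in 0 (adjusted p = 0.0495, 0.703 with an estimated correlation), and FAP (2.07), MCAM (1.46), PDPN (1.04) and ACTA2 (0.83) were among them. MCAM, PDPN and ACTA2 each had a probe set of the other sign (-0.17, -0.019 and -0.31). The pericyte call was kept in 6 of 18 settings. Removing the filter and leaving out the array labelled MGH87GSC 1 are among these and repeat the values of all arrays. By camera the call also ended where the median was larger, without U87 2 (0.34, adjusted p = 0.0536), without MGH87GSC 2 (0.31, adjusted p = 0.0505) and with quantile normalization (0.25, adjusted p = 0.0886). It ended as well without MGH87GSC 3 (0.13, adjusted p = 0.0573), with the mean over probe sets (0.13, adjusted p = 0.264), the strict filter (0.19, adjusted p = 0.218) and the control batch as a block (0.19, adjusted p = 0.0584). The p53 call also ended with median centring (0.37, adjusted p = 0.0664), quantile normalization (0.21, adjusted p = 0.0838), the strict filter (0.34, adjusted p = 0.211) and without MGH87GSC 3 (0.24, adjusted p = 0.0650). With the strict filter the mesenchymal (adjusted p = 0.0989), hypoxia (adjusted p = 0.126) and NF-kB (adjusted p = 0.0594) calls ended at medians of 0.27, 0.50 and 0.54, no smaller than before. The matrix protease call ended with the strict filter (0.13, adjusted p = 0.349) and with quantile normalization (0.22, adjusted p = 0.0971).

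**Figure D3:**
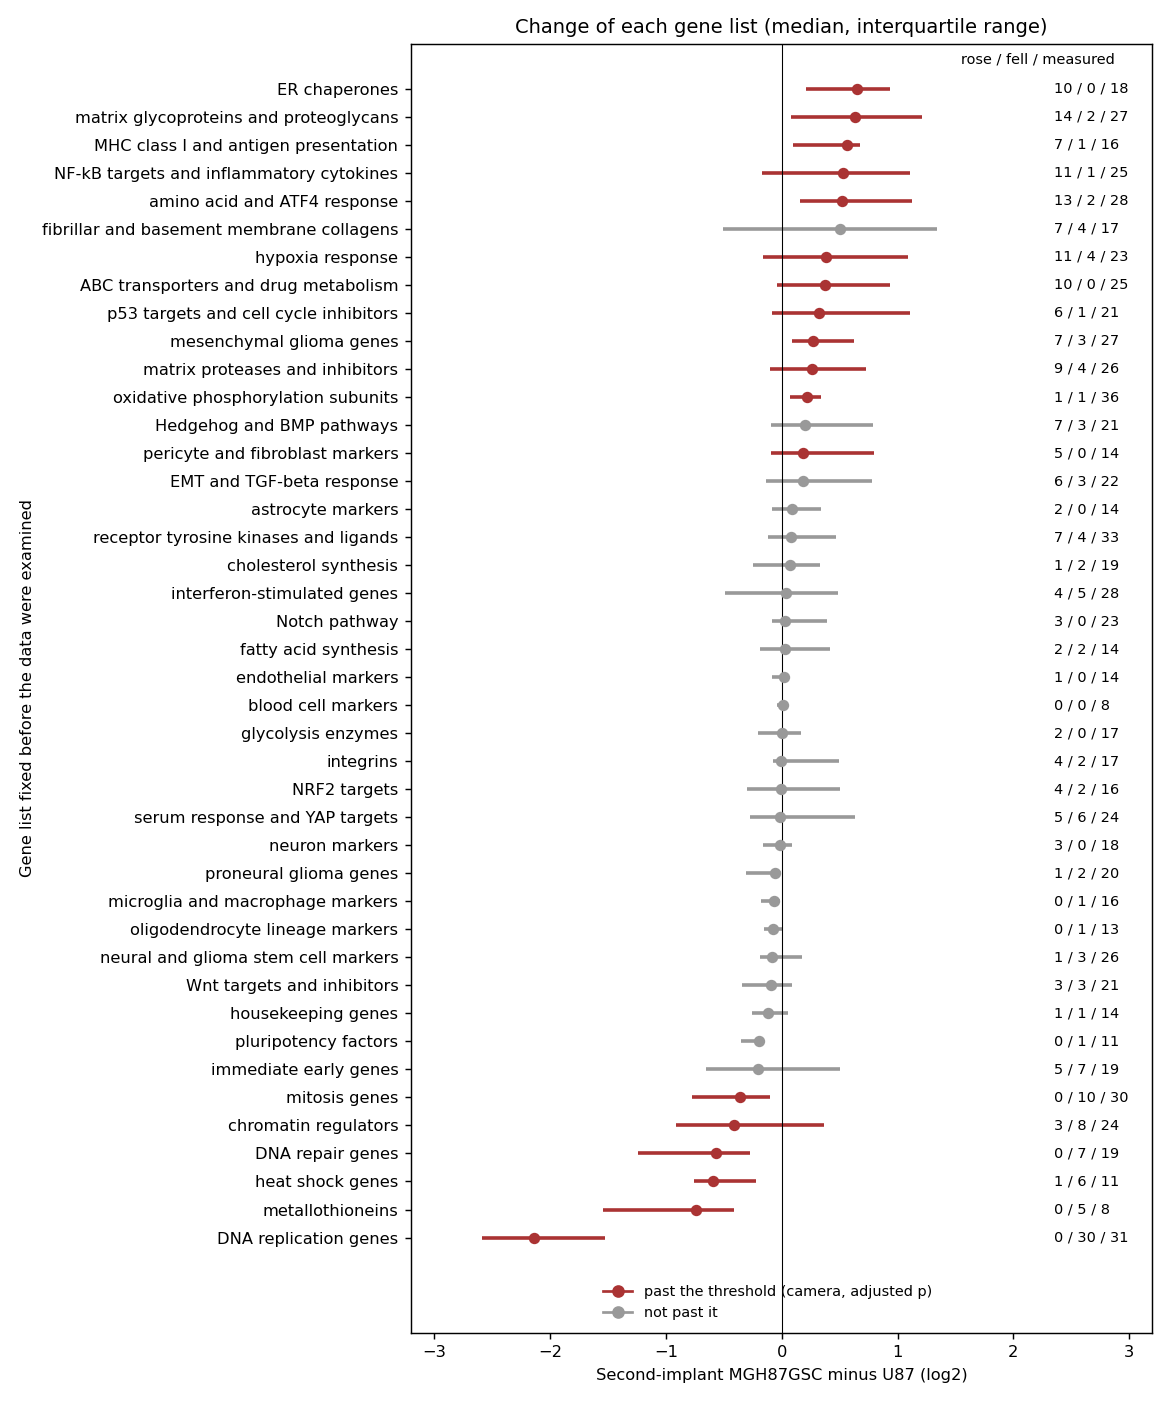
Median change (points) and interquartile range (lines) of each of 42 gene lists, second-implant MGH87GSC minus U87 on the log2 scale, with lists past the camera threshold in red. The numbers at the right count the genes that rose, that fell and that were measured, such as 0, 30 and 31 for DNA replication genes.

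Stem cell markers did not pass as a list in the second implant (26 measured, 1 rose and 3 fell, camera adjusted p = 0.440). PDPN rose, and SOX9 (-2.11), EZH2 (-2.05) and CD44 (-0.49, limma adjusted p = 0.0348) fell. The differences were -0.17 for PROM1, -0.10 for NES, -0.09 for SOX2, 0.21 for OLIG2, -0.32 for MSI1, 0.08 for NANOG, 0.07 for GFAP and -0.18 for EGFR, with limma adjusted p of 0.580 to 0.893. EGFR passed the threshold without U87 1 (-0.29, limma adjusted p = 0.0412) and on the 5 arrays outside the technical batch (-0.29, adjusted p = 0.00554). The signs of NES, SOX2, OLIG2, MSI1, NANOG, GFAP and EGFR each turned under at least 1 alternative. The pluripotency list did not pass (camera adjusted p = 0.0605), and MYC was its 1 member that fell (-0.87). Proneural glioma genes did not pass either (adjusted p = 0.258), with MAP2 up by 1.92 and the receptor gene PDGFRA (-2.57) and the chromatin remodeller gene CHD7 (-0.63) down. For PDGFRA 3 of 4 probe sets had the reported sign and their mean was -0.77, and for CD44 10 of 13 had it.

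Of the lists of other cell types, camera called the pericyte and fibroblast markers alone, and fry also the oligodendrocyte lineage markers (adjusted p = 0.0296). Neuron markers had 3 rises among 18 genes (MAP2, GAD1 at 1.01 and SNAP25 at 0.85; camera adjusted p = 0.770), and astrocyte markers 2 among 14 (ALDOC at 1.05 and GJA1 at 0.57; adjusted p = 0.354). Endothelial markers had 1 rise among 14 (ENG at 0.90; adjusted p = 0.944). Microglia and macrophage markers had 1 fall among 16 (CSF1R at -1.04; adjusted p = 0.423), oligodendrocyte lineage markers 1 among 13 (PDGFRA; adjusted p = 0.290) and blood cell markers none among 8 (adjusted p = 0.995).

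The count of genes in this comparison moved with single arrays and with the technical batch. It was 1408, 1438 and 1773 without MGH87GSC 4, 3 and 2, 2365 and 2181 without U87 2 and U87 3, and 7255 without U87 1. With the batch of the poly-A controls as a block limma called 6555 genes and 17 of the 18 lists stayed past the threshold, and among the 5 arrays outside that batch it called 9760 genes. All 3373 genes were among the calls in both of these fits. By fry 12 lists passed the threshold, 9 of the 18 and 3 that camera did not call, the proneural genes (adjusted p = 0.00409), collagens (0.0356) and oligodendrocyte lineage markers (0.0296). The mitosis (0.255), heat shock, MHC class I, chromatin and mesenchymal (0.0592 each), hypoxia and p53 (0.120 each), matrix protease (0.107) and oxidative phosphorylation (0.349) lists lost the call by fry. Leaving out any one of U87 2, U87 3 and MGH87GSC 2, 3 and 4 ended the calls of BUB1B, KIF11, CD44, CHD7, CYCS, GJA1, MYC, SNAP25, TAP2 and TP53I3. Leaving out any one of MGH87GSC 2, 3 and 4 ended those of AKR1C2, CCL2, GAD1, MMP1, PDPN, SDHA and XBP1, and, as did leaving out U87 3, those of HLA-E and INSIG2. The calls of ACTA2, FGF2, GSTT1 and MT1G ended without MGH87GSC 3 and without MGH87GSC 4, that of TRIB3 without MGH87GSC 3, that of HSP90AA1 without MGH87GSC 4 and that of CCL5 without MGH87GSC 2. With the mean over all probe sets of a gene ACTA2 (0.19), CHD7 (-0.32), FGF2 (0.70), GSTT1 (0.31), TAP2 (-0.34) and SNAP25 lost their calls. That mean was also smaller by more than 1.5 times for ABCA1 (0.97), AKR1C2 (0.76), CDKN1C (0.78), CHORDC1 (-0.56), COL1A1 (-0.43), EFEMP1 (2.347), HERPUD1 (1.07), MCAM (0.65), MT1G (-0.43), TET3 (-0.61), THBS1 (-0.53) and XBP1 (0.37), and larger for CYCS (-1.14). SNAP25 also lost its call with an intensity trend and robust prior. Without moderation of the variance 27 of the 116 named calls ended. Among them were those of CDCA8, CDK1, CDKN1B, FAP, MAP2, SLC30A1, XRCC2 and ZMAT3, which ended in no other setting. Median centring ended 17 named calls, among them those of CCL2, CD44, KIF11, MYC, SDHA and XBP1.

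The comparison of the first implant with U87 rested on the array labelled MGH87GSC 1. UHRF1 lay at 11.42 against 11.36 ± 0.24 (SD, n = 3) in U87, CD24 at 6.27 against 6.22 ± 0.17, INHBE at 5.25 against 5.16 ± 0.13 and CCNE2 at 10.06 against 9.99 ± 0.23. limma called 0 genes (smallest adjusted p = 0.956), and 1 gene had an unadjusted p under 0.05 where chance gives 989. The fit had no batch term, and U87 1 differed from U87 2 and U87 3 by a root mean square of 0.68 and 0.66. U87 2 and U87 3 differed by 0.13. The spread of the fit held this deviation of U87 1, so so few small p-values do not measure agreement with U87. The list median of DNA replication genes was 0.20 against U87 and -0.0041 against U87 2 and 3 alone. The design text would place this array in the first batch with 1 unnamed U87 array. With U87 1 in that place as a block, the fit compares the array labelled MGH87GSC 1 with U87 1 alone. The control differences of these arrays were 0.96 and 2.59, so that fit cannot separate the implant from the technical deviation of U87 1.

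The comparison of the first with the second implant rested on 1 array against 3, and it shares the second-implant arrays with the comparison of that implant with U87. The array labelled MGH87GSC 1 was higher than the second implant for UHRF1 (5.04 ± 0.25, SE), MCM10 (4.87), CCNE2 (4.16), MT1M (4.03) and DCLK1 (4.03). It was lower for IL1A (-3.82), CD24 (-3.81), INHBE (-3.81), GDF15 (-3.69) and KCNE4 (-3.65). limma called 1223 genes, 635 higher and 588 lower in the first implant, and these 10 genes had adjusted p of 0.00129 to 0.00286. These values rest on the spread of the other groups, because that of the first implant was not measured with 1 array. The size for MCM10 is also uncertain, because it was dim in the second implant. The first-implant array lay outside the second-implant arrays in 14180 genes, 71.7% against 50% by chance. By the design text implant and batch are confounded among the spheres, and with U87 2 or U87 3 placed in the first batch the count was 0. It ranged from 105 without MGH87GSC 4 (106 without MGH87GSC 3, 243 without MGH87GSC 2, 616 without U87 3, 710 without U87 2) to 5787 without U87 1.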

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

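The tests of the 3 patterns below were chosen after the patterns were seen, except that of held-out cell cycle genes, and the counts of other splits of the arrays for lists were also added later. A single array stood far from the other MGH87GSC arrays in 15 of 28 values examined, and in 13 of them it was the array labelled MGH87GSC 1. The values were the 10 measured genes named whatever they did, the control difference and the 17 lists past the threshold for MGH87GSC against U87. These lists were picked in the same data, so an array lying with U87 would stand out in them. The share expected by chance is thus no test of the 15. Chance gives about 5 in 100 such values, and over all 19775 genes the share was 15.2% (3014 genes, 2090 of them by the array labelled MGH87GSC 1 and 823 by MGH87GSC 2). The gap to the nearest array as a share of the range was 0.837 for EGFR and 0.942 for VEGFA, both by the array labelled MGH87GSC 1, and 0.922 for GFAP by MGH87GSC 3. For list means it was 0.887 for pluripotency factors, 0.959 for mesenchymal glioma genes, 0.915 for DNA replication genes, 0.925 for the amino acid and ATF4 response, 0.916 for ER chaperones and 0.947 for heat shock genes. It was 0.878 for metallothioneins, 0.836 for MHC class I and antigen presentation, 0.892 for matrix glycoproteins and proteoglycans, 0.832 for ABC transporters and drug metabolism and 0.887 for DNA repair genes, all by the array labelled MGH87GSC 1. For the 3′ minus 5′ difference of the poly-A controls it was 0.920, by MGH87GSC 2. The comparison of the array labelled MGH87GSC 1 with the second implant called 1223 genes, and 0 with U87 2 or U87 3 placed in the first batch. With 1 array of doubtful label and no spread of its own, this does not establish a difference between the implants.

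The array labelled MGH87GSC 1 lay with U87 2 and 3. Its difference from them was 0.923 times that between U87 2 and U87 3, as an array of U87 RNA under a wrong label would give. A shared technical batch alone is argued against, since MGH87GSC 3 and 4 share its control profile and lay 4.45 times as far from U87 2 and 3 as these from each other. That spheres of the first implant kept the parental profile stays open as a biological possibility, because it predicts the same expression values. By expression a wrong label and a kept parental profile cannot be told apart here. The control difference of 0.96 on this array is near those of U87 2 and 3, whereas the design text puts the first implant in another batch than the duplicate U87 arrays. If the design text is right and its batches differ in control signal, that goes against the label, but it rests on 1 array.

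U87 1 and MGH87GSC 2 stood apart from the other arrays of their groups. Their deviations correlated at r = 0.768 over genes, which are not independent replicates. Both had low 5′ control signal, as a technical batch in labelling or amplification would give. For GAPDH of the sample RNA the 3′ minus 5′ difference was -0.0052 and -0.024, within the -0.030 to 0.074 of the other arrays. For actin it was 0.17 and 0.19, against -0.10 to 0.080. A difference in the added controls themselves was not separated from one in labelling. The design text has 1 U87 array and the first implant in the first batch, and the array that shares the profile of U87 1 is MGH87GSC 2, with a control difference of 2.43. Exchanged implant labels of MGH87GSC 1 and 2 may account for that, although the expression values of MGH87GSC 2 lay with MGH87GSC 3 and 4. An exchange would make the array labelled MGH87GSC 1 a second-implant array. It differed from MGH87GSC 3 and 4 by a root mean square of 0.57, while these differed by 0.12. An exchange alone thus does not account for its place with U87. Nor would a kept parental profile of the first implant, since MGH87GSC 2 would then be the first implant. Under exchanged labels the arrays named second implant here would include an array of the first. The comparisons of the implants would then not hold as named. No biological explanation was tested for this pattern.

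DNA replication genes were lower in the second-implant arrays by a median of -2.14. The technical batch as the whole cause is argued against by a median of -2.36 among the arrays outside it. The median was -2.09 after centring and -2.19 after quantile normalization of the deposited values. The array medians lay between 5.87 and 6.12, so centring could hardly change it. The normalization before deposit was not tested. Cell cycle genes did not all fall alike. The planned mitosis list had a median of -0.36 (95% interval -0.69 to -0.22, bootstrap over genes) against -2.14 (-2.44 to -1.76) for replication genes. Outside the batch the medians were -0.54 and -2.36. Between MGH87GSC 2 and U87 1 they were -0.01 and -1.79, so the intervals over genes do not measure the spread between arrays. These medians go against a smaller share of cycling cells as the whole cause only if it lowers all cell cycle genes alike. That assumption was not tested, and the criterion was set after these medians were seen. The test written beforehand cannot decide, because its intervals overlap. Held-out G2 and M phase genes had a median of -0.46 (-0.83 to -0.28, 10 of 29 fell). Held-out S phase genes had a median of -1.28 (-1.49 to -0.70, 14 of 21 fell). A smaller share of cycling cells may still contribute. The implant itself and growth as spheres stay open and untested.

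The real split of the 7 arrays into 4 and 3 gave 0 genes, which all 35 of the 35 splits, the real one included, reach by necessity, so chance is not excluded and the count decides nothing. The highest of the other splits was 4461 genes, with MGH87GSC 2, 3 and 4 as the group of 3, which is the split of those arrays from U87 and the array labelled MGH87GSC 1 and points to a structure of the samples. The split of U87 2, U87 3 and the array labelled MGH87GSC 1 from the rest gave 3319. For the lists, 4 of 35 splits, the real one included, gave as many as the real 17 (highest other 19), so chance is not excluded. For the second implant against U87, the 10 splits of 3 against 3 are too few for a share under 0.05: the real split was 1 of 10 with 3373 genes (highest other 0) and 1 of 10 with 18 lists (highest other 17).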

How the results depend on the processing

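The batch read from the poly-A controls, the fits on the 5 arrays with high 5′ control signal, those without the array labelled MGH87GSC 1 beside them, and the lists for the second implant were added after seeing the data. All other alternatives were planned. The cause of a change was not tested unless stated. Removing the filter changed nothing because it had removed 3 probe sets. No detection calls were used, so how many genes lay above background is unknown.

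For MGH87GSC against U87, 0 genes were called in most fits. The count was 1419 (1393 higher and 26 lower) with the batch as a block and U87 1 in the first batch, 6555 with the control batch as a block and 9760 on the high-5′ arrays, both without the array labelled MGH87GSC 1, and 0 to 3373 over fits that left out 1 array. Lists past the threshold numbered 17, and 11 with the strict filter (fewer genes tested), 9 with quantile normalization, 0 with an estimated correlation, 0 by fry, 7 on the high-5′ arrays, 10 on these without the array labelled MGH87GSC 1, and 7 to 18 with 1 array left out.

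For the second implant against U87, the count of 3373 (2027 higher, 60.1%) became 7255 (47.1% higher) with the batch as a block and U87 1 in the first batch, 2181 with U87 3 there, 5343 (2750 higher and 2593 lower) with quantile normalization, 2069 (1352 higher and 717 lower) with median centring, 1927 without moderation, 6555 with the control batch as a block, 9760 on the high-5′ arrays, and 1408 to 7255 with 1 array left out. Lists numbered 18, and 10 with U87 1 in the first batch, 11 with the strict filter, 0 with an estimated correlation, 10 on the high-5′ arrays, and 10 to 19 with 1 array left out.

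For the first implant against U87 the count of 0 became 10728 with U87 1 in the first batch, and was 0 to 0 with 1 array left out. For the first against the second implant the count of 1223 became 11261 with U87 1 in the first batch, 0 with U87 2 and 0 with U87 3 there, 3248 with quantile normalization, 321 with median centring, 384 without moderation, 4203 with the control batch as a block, 8604 on the high-5′ arrays, and 105 to 5787 with 1 array left out.

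The replicate number as a block gave 0 genes and 19 lists for MGH87GSC against U87, 6556 genes and 11 lists for the second implant against U87, 8604 genes for the first implant against U87 and 9792 for the first against the second. The deviations of arrays with the same number correlated at -0.23, -0.68 and 0.18 over genes for numbers 1, 2 and 3, so the numbers do not pair the arrays, and these fits left 1 residual degree of freedom for the implants.

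No named gene past the threshold changed sign for the second implant, but many settings could not turn one. The groups of all 3373 called genes did not overlap, so leaving out arrays or blocking by the control batch keeps every sign. The design text's batch as a block amounts here to leaving out a U87 array. Of 2476 values 2295 kept direction and side, 163 lost the call and 3 kept direction and gained it, all for EGFR. A further 15 turned, of which MSI1 under the replicate block passed the threshold. Of 734 list values 567 kept both and 167 lost the call. For the second implant, removing the filter and leaving out the array labelled MGH87GSC 1 repeated the values of all arrays without a block. The kept values thus include settings that could change nothing, and the batch blocks count some fits again. The genes whose values turned were not past the threshold with all arrays and no block. For the second implant, under the replicate block MSI1 was 0.51 (higher, adjusted p = 0.0137 by limma with 1 residual degree of freedom), OLIG2 -0.030 and SOX2 0.029. With U87 1 in the first batch, and without U87 1, MSI1 was 0.32 and SOX2 0.064. With U87 3 there, and without U87 3, NANOG was -0.0045. With the mean of all probe sets EGFR was 0.16, GFAP -0.11 and NANOG -0.063. On the high-5′ arrays MSI1 was 0.062 and SOX2 0.13. Over fits with 1 array left out NES ran from -0.24 (without MGH87GSC 2) to 0.056 (without MGH87GSC 3), MSI1 from -0.66 (without U87 2) to 0.32 and SOX2 from -0.19 (without U87 2) to 0.064. For MGH87GSC against U87, the mean of all probe sets gave 0.063 for EGFR, -0.13 for GFAP and -0.12 for NANOG. MSI1 ran from -0.74 (without U87 2) to 0.24 (without U87 1), NANOG from -0.027 (without U87 3) to 0.15 (without U87 1) and NES from -0.15 (without MGH87GSC 2) to 0.044 (without MGH87GSC 3). On the high-5′ arrays MSI1 was 0.037 and SOX2 0.019, and without the array labelled MGH87GSC 1 as well they were 0.062 and 0.13.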

Other observations

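Lists that did not pass as a whole in the second implant held genes that moved strongly in both directions, and the genes named in this paragraph were chosen after their values were seen. In the Hedgehog and BMP list (7 of 21 rose, 3 fell, camera adjusted p = 0.102), the inhibitor-of-differentiation genes ID1 (3.03 ± 0.34, SE) and ID4 (1.26 ± 0.14) rose with ID3, while the ligand gene BMP2 (-1.99 ± 0.13) and the activin and BMP antagonist gene FST (-1.48 ± 0.16) fell. Collagens divided (7 of 17 rose, 4 fell, adjusted p = 0.0936): COL11A1 (2.57) and COL8A1 (2.36) rose with COL1A2 and COL5A1, and COL15A1 (-1.77), COL4A2 (-1.03) and COL1A1 (-0.98) fell. COL11A1 was dim in U87 (10.7th percentile of probe sets), so the size of its rise is uncertain, and its mean over probe sets was 1.71. COL8A1, COL1A1 and ID4 each had a probe set of the other sign (-0.17, 0.19 and -0.23), and the mean for COL8A1 was 1.40. COL1A1 and COL1A2, which encode the chains of 1 collagen, went in opposite directions. Of 19 immediate early genes 5 rose and 7 fell (adjusted p = 0.534), with FOS (-2.07) and the ERK phosphatase gene DUSP6 (-1.48) lower and JUNB (1.15) higher. Limma adjusted p of these genes lay between 0.000414 and 0.00822.

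Other lists past no threshold held named genes as well, again chosen after their values were seen. The cyclin D1 gene CCND1 (-1.92) and the Wnt inhibitor gene DKK1 (-1.47) fell in the Wnt list (3 of 21 rose, 3 fell, camera adjusted p = 0.333). TGFB2 (2.28) and TWIST1 (1.93) rose in the EMT and TGF-beta list (6 of 22 rose, 3 fell, adjusted p = 0.05002). HMOX1 (1.93) rose in the NRF2 list (4 of 16 rose, 2 fell, adjusted p = 0.802), and FGF2 (1.23) rose among receptor tyrosine kinases and ligands (7 of 33 rose, 4 fell, adjusted p = 0.375). CDKN1B (1.11), which encodes the CDK inhibitor p27, rose beside CDKN1A and CDKN1C, and TRIB3 (1.79) rose in the ATF4 list. The remaining lists were interferon-stimulated genes (4 of 28 rose, 5 fell), serum response and YAP targets (5 and 6 of 24), integrins (4 and 2 of 17), Notch pathway (3 and 0 of 23), glycolysis enzymes (2 and 0 of 17), cholesterol synthesis (1 and 2 of 19), fatty acid synthesis (2 and 2 of 14) and housekeeping genes (1 and 1 of 14), with adjusted p of 0.440 to 0.985.

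Several known FOXO target genes, such as TXNIP and CDKN1B, were among the genes that rose, and the hypothesis that FOXO targets rise as a group was tested on 20 others written down before their values were seen. Their median change in the second implant was 0.45, at the 99.4th percentile of 10000 random lists matched on mean expression (95% of which lay between -0.20 and 0.34). This test used the fit of all arrays only. It was not repeated without U87 1, whose removal ended the calls of 8 higher lists. Of the 20 genes 8 rose and 0 fell, among them PDK4 (1.68 ± 0.25, SE), ULK1 (1.67 ± 0.22), HBP1 (1.43 ± 0.27), PINK1 (1.38 ± 0.19), CAT (0.96 ± 0.13) and SESN3 (0.95 ± 0.20). The result is consistent with a shared rise of FOXO targets as a hypothesis, but genes are not independent replicates, many of these genes respond to other regulators, and FOXO activity was not measured.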
